A study of Mus musculus with 6 samples.

How the data were processed

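Total RNA was taken from whole liver of male mice with floxed Ephb2, without Cre (WT, n = 3) or with the tamoxifen-inducible Pdgfrb-CreERT2 driver (KO, n = 3), after 8 weeks on the choline-deficient high-fat diet. Per the labels' protocols, RNA was enriched for polyadenylated transcripts, made into libraries with a directional kit and sequenced on an Illumina NovaSeq. The authors deposited whole-number read counts per Ensembl gene, 1 column per sample, with no normalization. STAR 2.7.6a, featureCounts 1.6.3 and DESeq2 1.30.0 and the builds GRCm38 and mm10 are named, without roles, per the submitters' processing notes. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads of antisense pairs and of near-identical genes can therefore be shared between them.

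Gene symbols and coordinates came from GENCODE M21 on GRCm38, which held 52083 of the 55416 gene IDs (94.0%). The 3333 unmatched IDs took 0.835 to 1.15% of the counts of a library, and 110 of them were among the genes tested. Whether M21 is the release the authors counted with is not settled, so gene bounds could differ slightly from theirs. Total counts were 21411113, 23100862 and 22199501 in WT replicates 1 to 3 and 22463821, 26339251 and 21160690 in KO replicates 1 to 3. The 20 most abundant genes took 17.6 to 20.2% of the counts and mitochondrially encoded genes 2.04 to 3.19%. Counts of 25807 genes were 0 in every library. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom from 11.4 to 77.1, so each counted as 1 replicate.

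The main test was edgeR 4.0.16 (glmQLFit without robust estimation and glmQLFTest) in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total count 15), which left 17083 genes, genotype as the sole term and Benjamini-Hochberg adjustment at 0.05. Levels are CPM scaled by TMM, given as mean ± SD, and logged levels used a prior count of 2. Intervals are 95% intervals. The common biological coefficient of variation was 0.171 and the median SE of a log2 fold change 0.159. An exact two-sided permutation test was run on the CPM of Ephb2, for which 3 against 3 libraries allow no p below 0.1.

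The design, the alternatives, the rule for naming genes and 44 gene lists were fixed before the data were examined, except where said otherwise. Of the lists, 43 had at least 5 members past the filter and were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over the 43 lists. The list of pancreas genes had 2 members past the filter and was not tested. For each list the estimated correlation and fry were run too, and members were also adjusted over the list alone. The rule named Ephb2, then up to 8 genes per direction among genes past the threshold without overlap between the genotypes, a mean CPM of at least 1 and an established symbol. Since none passed, its fallback took the 5 with the smallest p per direction and kept the other conditions. It also named the 4 members with the smallest p from each of 4 main lists and 2 from each other list that passed, some of which are not reported here. Genes named outside this rule (Col1a1, Col1a2, Col3a1, Acta2, Lrat, Saa1, Orm2, S100a8, Igfbp1, Rab30, 1810055G02Rik, the genes called with a library left out and genes of other splits) were chosen after their values were seen.

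Alternatives were DESeq2 size factors, library size only and upper-quartile scaling, no count filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, robust fitting, the replicate number as a block, leaving out each library, mitochondrially encoded genes or the 20 most abundant genes, an adjusted p under 0.1 and a test against a fold of 1.5. An acute phase covariate and 1 surrogate variable from sva 3.50.0 were added after seeing the data. DESeq2 gave no adjusted p for 15502 genes and one for 14107, and genes without one were not counted. The procedure was tested on simulated counts with the means and library sizes of these samples, in 5 runs of 17083 genes with 200 changed. The 200 were drawn from genes with an average CPM of at least 1, besides a planted list. edgeR recovered 14.9% of 1.5-fold, 62.1% of 2-fold and 96.4% of 4-fold changes with 47 false calls in all. DESeq2 recovered 33.4%, 74.3% and 97.6% with 188 false calls. A planted list raised 1.25-fold was found by camera's preset test in 5 of 5 runs, with an estimated correlation in 0 and by fry in 4. Simulated genes were drawn independently, so these runs do not measure false list calls among correlated genes.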

Results

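RNA from whole liver was sequenced as 6 libraries from male mice, 3 per genotype. All animals carried floxed Ephb2, which encodes a receptor tyrosine kinase that binds ephrin-B ligands on neighbouring cells. The libraries called WT here came from floxed animals without Cre. Those called KO came from floxed animals with Pdgfrb-CreERT2, a tamoxifen-inducible recombinase expressed in stellate cells, pericytes and other cells with an active Pdgfrb promoter. The mice were 8 to 10 weeks old and received tamoxifen for 5 days. They were then kept for 8 weeks on a choline-deficient, amino-acid-defined diet, which gives mice a fatty, inflamed and scarred liver. It held 45% of its calories as fat, 0.1% methionine and 1% cholesterol. Total counts ran from 21411113 to 23100862 in the WT libraries and from 21160690 to 26339251 in the KO libraries. The labels number the samples within each genotype and do not say more about how the replicates relate, so the p-values measure the spread between these samples. The design holds 1 comparison, which asks how the liver transcriptome under this diet differs when Ephb2 is deleted in Pdgfrb-expressing cells. No group carried Cre without floxed Ephb2, so an effect of Cre cannot be told apart from one of the deletion. The title of the series names fibrosis as the outcome of interest.

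Ephb2 was measured first, as the targeted gene. Its level was 10.1 ± 2.14 CPM (TMM-scaled, SD, n = 3) in WT and 7.28 ± 1.46 CPM (SD, n = 3) in KO liver, a log2 fold change of -0.46 (95% interval -0.94 to 0.01). The WT libraries held 9.46, 8.28 and 12.4 CPM and the KO libraries 6.01, 8.87 and 6.95 CPM, so the genotypes overlapped. The difference did not pass edgeR's quasi-likelihood test (adjusted p = 0.850), and a two-sided exact permutation test gave p = 0.2 where 3 against 3 libraries cannot go below 0.1. Ephb2 (ENSMUSG00000028664) lies on chromosome 4 of GRCm38 at positions 136647539 to 136835988 on the minus strand, with up to 16 exons in a transcript. Other liver cells keep the gene in this design, and the count covers all its exons, whether or not they lie in the deleted part. The value therefore checks the labels only weakly.

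No gene passed the threshold between the genotypes. The genes with the smallest p were named among those with an established symbol, a mean CPM of at least 1 and no overlap between the genotypes. Higher in KO liver were Hhex, a homeobox transcription factor of endoderm and endothelium, and Xist, the noncoding RNA that coats the inactive X chromosome. Srebf1, the transcription factor that drives fatty acid synthesis, lay higher too. Cx3cl1, the chemokine fractalkine, and Slc52a3, a riboflavin transporter, also belonged to them. Those that lay lower were Klf10, a zinc finger factor induced by TGF-beta and by fasting signals, Angptl4, a secreted inhibitor of lipoprotein lipase and a PPAR target, and Pim3, a serine/threonine kinase. Iqgap3, a scaffold protein of dividing cells, and Nrbf2, a subunit of an autophagy complex, lay lower too. Hhex stood at 62.4 ± 3.22 CPM in WT and 89.4 ± 4.92 CPM in KO (SD, n = 3 each) and Srebf1 at 175 ± 31.9 and 307 ± 26.9 CPM. Angptl4 stood at 136 ± 28.2 and 60.9 ± 13.8 CPM and Klf10 at 40.1 ± 5.26 and 22.9 ± 1.80 CPM. edgeR's quasi-likelihood test called 0 of 17083 genes (smallest adjusted p = 0.850), with 886 genes at an unadjusted p under 0.05 where 854 are due by chance. Of the 886, 527 were higher and 359 lower in KO liver, and this balance depends on the scaling, with 804 of 957 higher by library size alone. The count at an unadjusted p under 0.05 was 1858 without WT replicate 2 and 452 without KO replicate 3. limma-voom also called 0 genes, with 881 at an unadjusted p under 0.05, while DESeq2 called 8. Without WT replicate 3, edgeR called 2 genes, 1 higher and 1 lower, and 0 without any of the other libraries. The CPM of the genotypes did not overlap in 1898 genes, 11.1% of those tested, and chance gives 10%.

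**Figure D1:**
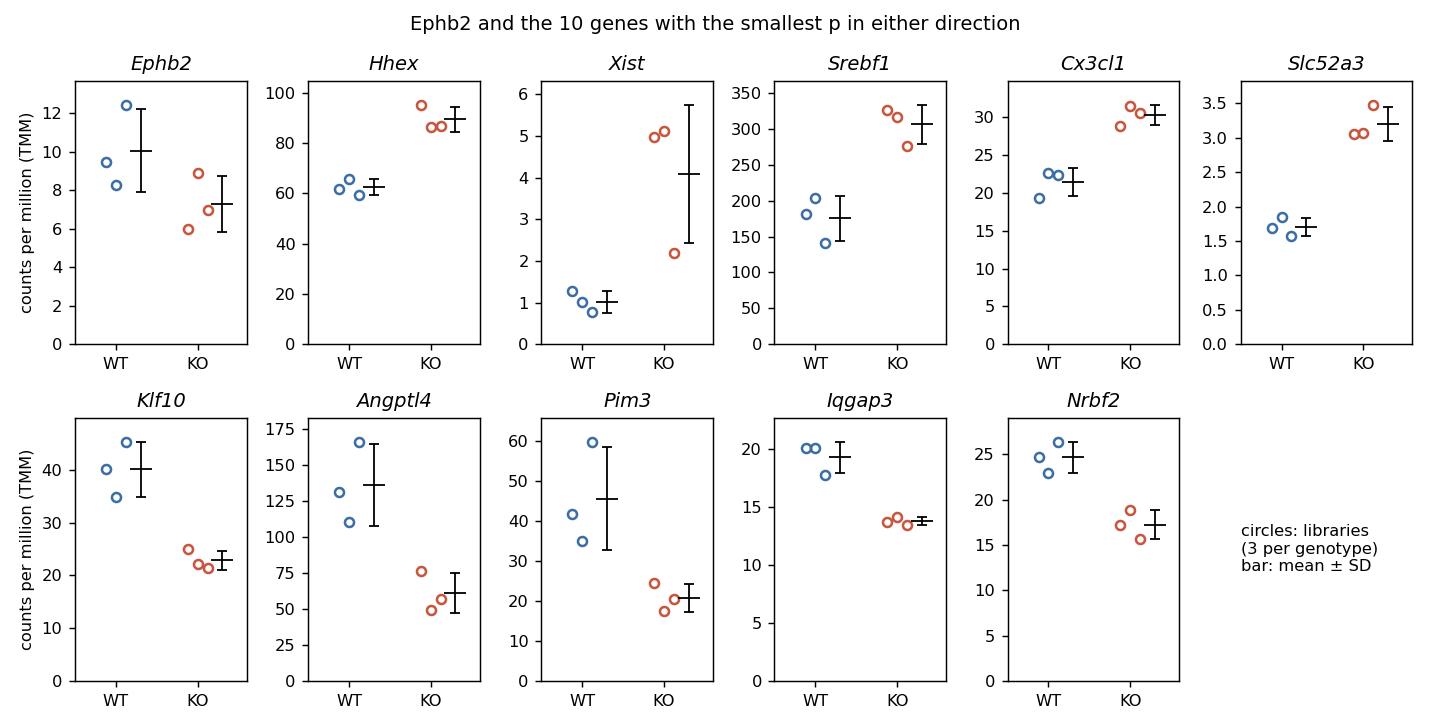
CPM (TMM-scaled, linear axes from 0) of Ephb2 and of the 10 genes named by smallest p, with circles for the 3 WT and 3 KO libraries and bars for the mean ± SD. Ephb2 overlaps between the genotypes, at 8.28 to 12.4 CPM in WT and 6.01 to 8.87 CPM in KO liver. The other 10 genes were chosen among those without overlap, 11.1% of the genes tested.

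The 8 genes that DESeq2's Wald test called after Benjamini-Hochberg adjustment comprised 3 higher in KO liver, Hhex (log2 fold change 0.51, DESeq2 adjusted p = 0.00967), Srebf1 (0.80, adjusted p = 0.00222) and Xist (adjusted p = 0.00253). The 5 lower were Angptl4 (-1.17, adjusted p = 0.000352), Klf10 (-0.82, adjusted p = 0.000769), Pim3 (-1.14, adjusted p = 0.00222), Rab30 (-1.03, adjusted p = 0.0321), a small GTPase of the Golgi, and the uncharacterised 1810055G02Rik (-0.55, adjusted p = 0.0228). All 8 had an edgeR adjusted p of 0.850. Without a filter on low counts, edgeR called 3 genes, Angptl4, Klf10 and Pim3, all lower in KO liver at an adjusted p of 0.0422. In simulated counts with the means and spread of these libraries and 200 planted changes per run, DESeq2 made 188 false calls over 5 runs and edgeR made 47. DESeq2 found 112, 249 and 322 true changes of 1.5-fold, 2-fold and 4-fold there, and edgeR 50, 208 and 318. The share of false calls thus lay above 0.05 for both, and further above it for DESeq2. This share depends on the number of true changes, so these counts do not tell how many of the 8 are false. edgeR recovered 62.1% of 2-fold and 14.9% of 1.5-fold changes, and DESeq2 74.3% and 33.4%. The changed genes had an average CPM of at least 1, and recovery also depends on the number of true changes. These shares therefore do not give the power of the test between the genotypes. Hhex lies on chromosome 19 (37434810 to 37440731) and Srebf1 on chromosome 11 (60199089 to 60222581) of GRCm38. Angptl4 lies on chromosome 17 (33773750 to 33781830), and Klf10 (38291463 to 38300706) and Pim3 (88862186 to 88865726) on chromosome 15.

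The libraries of each genotype differed widely among themselves in hepatocyte acute phase genes, whose products are secreted in response to inflammatory cytokines. Saa1, serum amyloid A, was at 423, 51.6 and 595 CPM in the WT libraries and at 57.3, 1857 and 80.4 CPM in the KO libraries, and Saa1 and Saa2 are near-identical copies that can share reads. Orm2, orosomucoid, was at 548, 76.1 and 717 CPM in WT and at 53.9, 1083 and 76.0 CPM in KO liver. Thus WT replicates 1 and 3 and KO replicate 2 held high acute phase RNA and the other 3 libraries held little. S100a8, a calcium-binding protein of neutrophils, followed the same libraries with 11.9, 4.29 and 30.4 CPM in WT and 5.71, 22.3 and 4.50 CPM in KO. The first principal component held 43.1% of the variance between libraries.

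Of 43 gene lists fixed beforehand, 22 passed camera with its preset correlation after Benjamini-Hochberg adjustment, 6 higher and 16 lower in KO liver. The preset of 0.01 treats genes of a list as nearly independent. Among the 22 lists the estimated correlation ran from 0.025 for lipid droplet genes to 0.90 for neutrophil markers. It was 0.49 for fatty acid oxidation and 0.68 for Kupffer cells. Over the libraries, the 95% interval of the list mean included 0 for fatty acid oxidation (-0.96 to 0.25) and Kupffer cells (-1.52 to 0.53). Among the 22 it excluded 0 only for lipid droplets (-0.41 to -0.003) and sex chromosomes (0.20 to 0.72). The interval of the female-biased list, which did not pass camera, excluded 0 as well (-0.41 to -0.08). These intervals are not adjusted over the lists. No list passed with the correlation between genes estimated from the data (smallest adjusted p = 0.570 with an estimated correlation). The self-contained test fry passed 0 lists (smallest adjusted p = 0.477). Many lists share the 0.570 after adjustment, so it does not single out any of them. In simulated counts a planted list was found with an estimated correlation in 0 of 5 runs and by fry in 4. The simulated genes were drawn independently, whereas the estimated correlation among the 22 lists reached 0.90. These runs therefore do not give the power of either test for the real lists. A miss by either test does not show that a list is unchanged. No member of any list passed edgeR's test over all genes, and adjusted over the list alone 3 members did: Xist, Srebf1 and Bbc3. The latter adjustment covers each list by itself and does not correct over the 43 lists. Other splits of the same 6 libraries into 3 and 3 put between 10 and 21 lists past the same threshold. The calls of 8 lists stood under every other setting and with any library left out. They were those of fatty acid oxidation, cholangiocytes, cell cycle, Kupffer cells, choline and methionine metabolism, lipid droplets, immediate early genes and sex chromosomes. All these settings kept the preset correlation, so they do not test it. Scaling by library size alone shifted the median of all genes to 0.07 and the lists with it, and ended none of the 22 calls. By it the mean log2 fold change went from -0.11 to -0.024 for oxidative phosphorylation, -0.092 to -0.0074 for lipoprotein export, -0.15 to -0.061 for hepatocyte, -0.16 to -0.076 for periportal and -0.16 to -0.085 for quiescent stellate genes. It went from -0.19 to -0.11 for cell cycle, -0.17 to -0.089 for choline and methionine, -0.22 to -0.14 for lipid droplet, -0.21 to -0.12 for immediate early, -0.20 to -0.11 for p53 and -0.25 to -0.16 for acute phase genes. Lists that lay higher moved up, from 0.088 to 0.17 for TGF-beta and from 0.14 to 0.22 for developmental signalling.

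**Figure D2:**
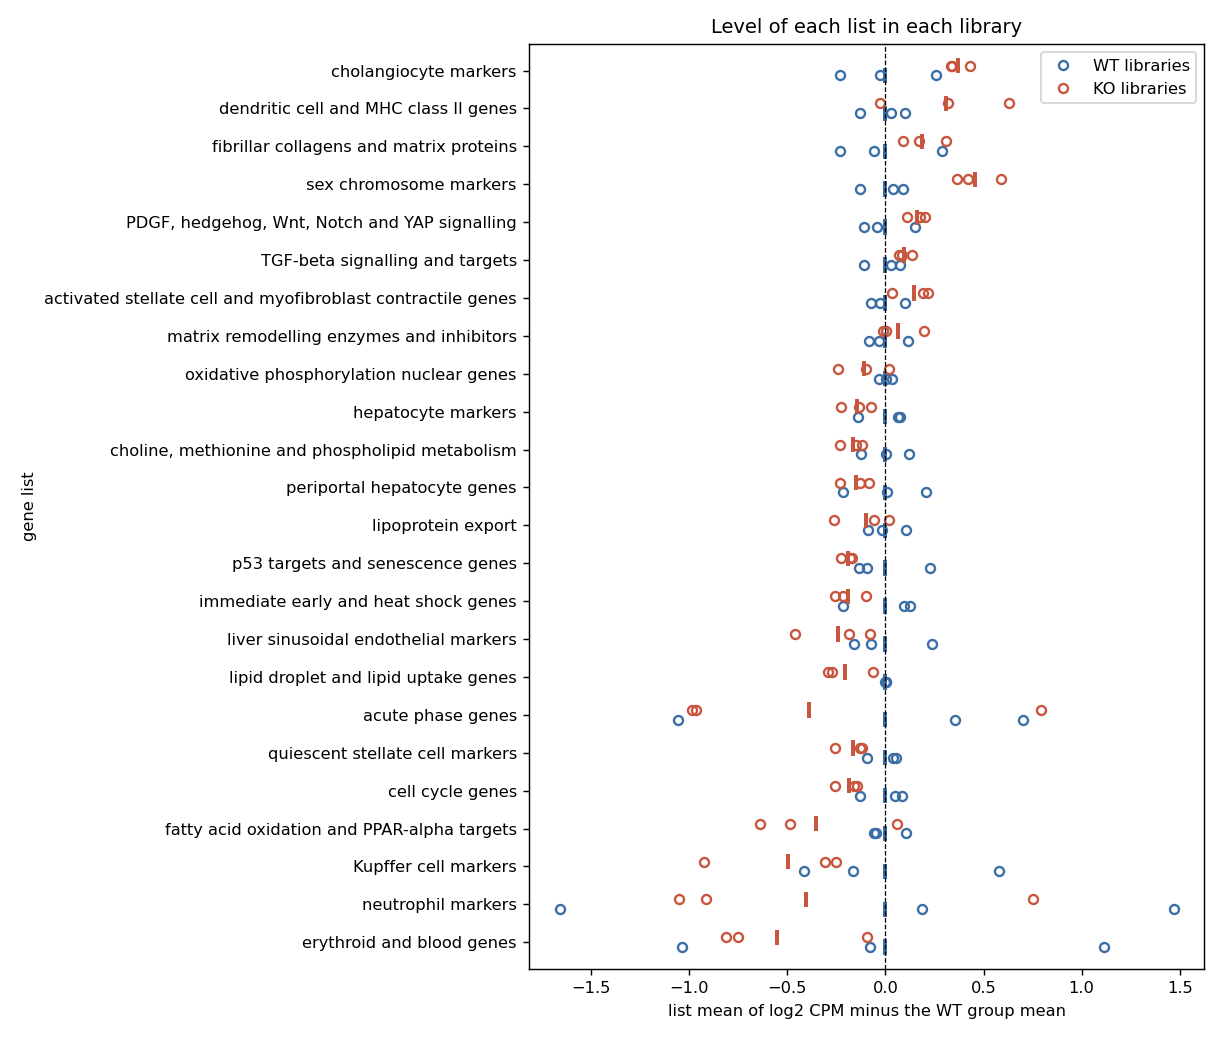
Mean log2 CPM over each list in each library, minus the mean of the WT libraries (x axis, log2 units), for the 22 lists past camera's preset test and the other 2 main lists, with circles for libraries and bars for the mean of each genotype. The cholangiocyte list lies apart (WT 4.63 to 5.12, KO 5.19 to 5.29 mean log2 CPM). The cell cycle, lipid droplet, p53, quiescent stellate and sex chromosome lists do not overlap between the genotypes either. For any given list, chance gives no overlap in 10% of cases. The acute phase list spans 7.73 to 9.49 in WT and 7.80 to 9.58 in KO libraries.

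Genes of scar matrix lay slightly higher in KO than in WT liver. In the list of fibrillar collagens and matrix proteins, 21 of 24 members had a positive log2 fold change, with a median of 0.14, and the list passed camera's preset test (adjusted p = 0.00245; adjusted p = 0.570 with an estimated correlation). No member passed edgeR's test, over all genes or adjusted over the list alone. Col1a1 and Col1a2, which encode the chains of type I collagen, were at 665 ± 148 and 406 ± 86.0 CPM in WT and 782 ± 159 and 489 ± 93.0 CPM in KO liver (SD, n = 3), log2 fold changes of 0.23 (SE 0.21) and 0.27 (SE 0.19). Col3a1 stood at 0.12 (SE 0.24). The members with the smallest p were Col15a1 (0.32, SE 0.10), a basement membrane collagen, Postn (-0.53, SE 0.18), the matricellular protein periostin, which lay lower, Mfap4 (0.96, SE 0.37) and Thbs2 (0.25, SE 0.12). Without WT replicate 1 the list no longer passed (adjusted p = 0.725, against 6.97e-08 to 0.725 over the libraries left out). Its mean log2 fold change of 0.17 went to 0.050 without WT replicate 1, 0.34 without WT replicate 2, 0.10 without KO replicate 3 and 0.081 with 1 surrogate variable. Among the 9 other splits of the libraries, 4 gave the list a smaller adjusted p than the genotypes did (6.99e-09, 1.57e-06, 7.2e-06 and 0.000666). The list mean overlapped between the genotypes, at 6.56, 7.08 and 6.74 log2 CPM in WT and 6.96, 6.88 and 7.10 in KO libraries. Bile duct markers were also lowest in WT replicate 1 and highest in KO replicate 3, at 4.63, 5.12 and 4.83 in WT and 5.20, 5.19 and 5.29 in KO libraries, with a mean log2 fold change of 0.35.

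**Figure D3:**
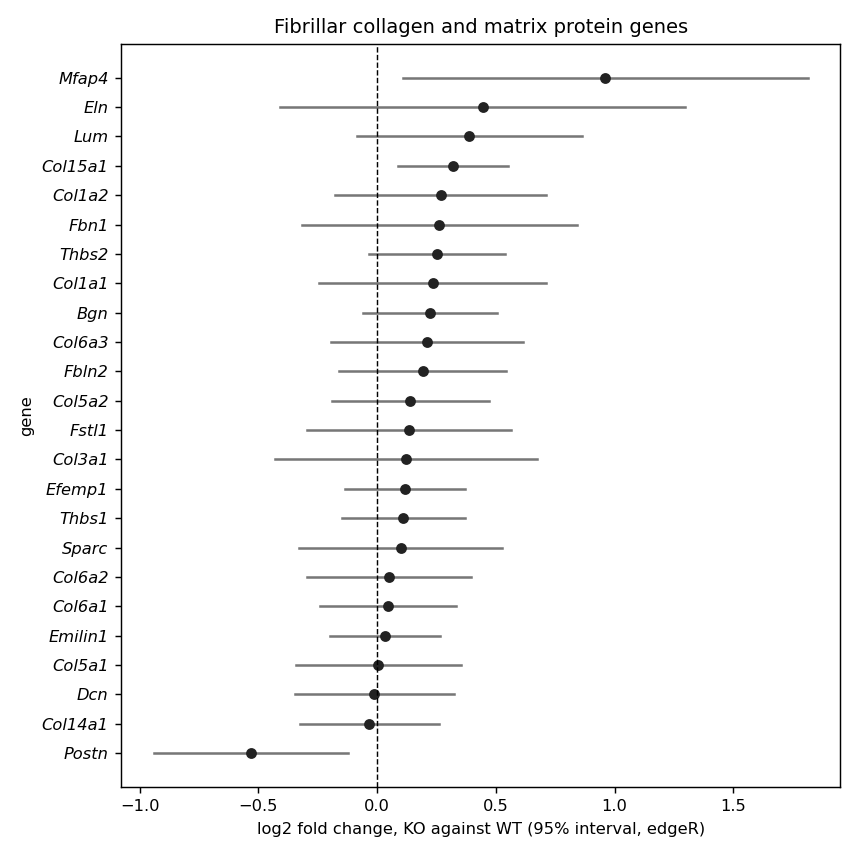
Log2 fold change in KO against WT liver (x axis) with its 95% interval from edgeR for the 24 members of the fibrillar collagen and matrix protein list (y axis), ordered by fold change. Mfap4 is at the top with 0.96 (0.11 to 1.81) and Postn at the bottom with -0.53 (-0.94 to -0.12), and most intervals include 0.

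Genes of TGF-beta signalling, the main pathway that drives stellate cells to make matrix, also passed as a list, with 16 of 26 members positive and a median of 0.07 (camera adjusted p = 0.0273; adjusted p = 0.570 with an estimated correlation). Inhba, the activin A subunit, was at a log2 fold change of 0.47 (SE 0.15), the ligand Tgfb3 at 0.39 (SE 0.13), the feedback gene Pmepa1 at 0.33 (SE 0.12) and Inhbb at -0.65 (SE 0.25), and 0 of the 26 passed adjusted over the list alone. Leaving out WT replicate 1 (adjusted p = 0.494), KO replicate 1 (0.0708) or KO replicate 2 (0.0613) ended this call. The contractile and myofibroblast genes of activated stellate cells did not pass (10 of 19 positive, median 0.04, camera adjusted p = 0.134), nor did matrix remodelling enzymes (14 of 26 positive, median 0.03, adjusted p = 0.134). Acta2, smooth muscle actin, was at 14.2 ± 2.13 CPM in WT and 13.1 ± 3.11 CPM in KO liver (SD, n = 3). In the myofibroblast list the smallest p fell to Mgp (log2 fold change 1.17, SE 0.32), matrix Gla protein, Pdgfra (0.34, SE 0.14), Spp1 (0.38, SE 0.18), osteopontin, and Loxl1 (0.36, SE 0.19). The lists of bile duct and of lipid-associated macrophage markers hold Spp1 too. Among remodelling genes the smallest p fell to the metalloproteinase inhibitors Timp3 (0.57, SE 0.19) and Timp2 (0.38, SE 0.13), to Ctsk (0.29, SE 0.12), cathepsin K, and to Mmp2 (0.49, SE 0.22). No member of either list passed edgeR's test, over all genes or adjusted over the list alone. The remodelling list passed once WT replicate 3 (adjusted p = 0.0186), KO replicate 1 (0.0244) or KO replicate 3 (0.0447) was left out. The myofibroblast list passed without KO replicate 1 (adjusted p = 0.0398).

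Markers of quiescent stellate cells, the vitamin A storing state, fell as a list, with 13 of 20 members negative and a median of -0.23 (camera adjusted p = 0.0488; adjusted p = 0.570 with an estimated correlation). The smallest p were those of the collectin Colec10 (-1.73, SE 0.54) and of Cygb (0.31, SE 0.10), cytoglobin, which lay higher. Lrat, the enzyme that esterifies retinol, was at a log2 fold change of -0.42 (SE 0.16, n = 3). The list is close to the threshold, and limma-voom (adjusted p = 0.0740), the robust fit (0.0588), the stricter count filter (0.0559), leaving out the 20 most abundant genes (0.0505) or leaving out WT replicate 2 (0.468), KO replicate 2 (0.0596) or KO replicate 3 (0.0715) ended its call.

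Marker RNA of other liver cell types passed camera's preset test as lists in both directions, without a member past edgeR's test. Bile duct (cholangiocyte) markers rose as a list, with all 13 members positive and a median of 0.38 (camera adjusted p = 2.41e-08; adjusted p = 0.570 with an estimated correlation). Pkhd1, the gene of fibrocystin, was at 197 ± 47.3 CPM in WT and 297 ± 63.3 CPM in KO liver (SD, n = 3). Kupffer cell markers fell, with all 14 negative and a median of -0.49 (camera adjusted p = 4.12e-06; adjusted p = 0.570 with an estimated correlation). The resident macrophage genes Clec4f and Vsig4 were at log2 fold changes of -1.03 (SE 0.41) and -0.98 (SE 0.39). The list mean overlapped between the genotypes (WT 4.99 to 5.99, KO 4.48 to 5.15 log2 CPM). Its mean log2 fold change of -0.56 went to -0.18 without WT replicate 3 and to -0.22 with 1 surrogate variable. Dendritic cell and MHC class II genes rose, with 15 of 16 positive and a median of 0.27 (camera adjusted p = 0.000195; adjusted p = 0.570 with an estimated correlation), led by Itgae (0.72, SE 0.22) and Flt3 (0.47, SE 0.17). The call ended without KO replicate 1 (adjusted p = 0.170). Sinusoidal endothelial markers fell, with 15 of 17 negative and a median of -0.18 (camera adjusted p = 0.000667; adjusted p = 0.570 with an estimated correlation). Among them were Oit3 (-0.53, SE 0.21) and the hyaluronan receptor Lyve1 (-1.01, SE 0.47), and the call ended without WT replicate 3 (adjusted p = 0.0712). In each of these 4 lists no member passed edgeR's test adjusted over the list alone.

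Of the metabolic lists that fell under camera's preset test, 4 are described here and lipoprotein export below. Fatty acid synthesis (adjusted p = 0.676), cholesterol (0.221), bile acid (0.218) and xenobiotic genes (0.537) did not pass. Fatty acid oxidation genes and PPAR-alpha targets fell as a list, with 22 of 24 negative and a median of -0.26 (camera adjusted p = 2.14e-08; adjusted p = 0.570 with an estimated correlation). Pdk4, the kinase that shuts off pyruvate oxidation, was at 81.4 ± 47.5 CPM in WT and 25.2 ± 5.84 CPM in KO liver (SD, n = 3), a log2 fold change of -1.69 (SE 0.38). Cyp4a31, one of several near-identical Cyp4a genes that can share reads, was at -0.83 (SE 0.24). The list mean was 7.33 to 7.49 log2 CPM in WT and 7.44, 6.74 and 6.90 in KO libraries, so KO replicate 1 lay among the WT libraries. The mean log2 fold change of the list went from -0.34 to -0.59 without KO replicate 1 and to -0.22 without KO replicate 2. Lipid droplet genes fell, with 12 of 17 negative and a median of -0.21 (camera adjusted p = 0.000912; adjusted p = 0.570 with an estimated correlation), among them the droplet coat gene Plin5 (-0.50, SE 0.15) and Pnpla2 (-0.48, SE 0.16), adipose triglyceride lipase. Without a count filter their mean log2 fold change went from -0.22 to 0.02, although the test still called the list lower. Choline, methionine and phospholipid genes fell, with 20 of 22 negative and a median of -0.14 (camera adjusted p = 0.000768; adjusted p = 0.570 with an estimated correlation). Mat1a, which makes S-adenosylmethionine in hepatocytes, was at -0.50 (SE 0.18) and Cth, cystathionine gamma-lyase, at -0.25 (SE 0.10). Nuclear genes of oxidative phosphorylation fell, with 24 of 25 negative and a small median of -0.11 (camera adjusted p = 0.00142; adjusted p = 0.570 with an estimated correlation), including Cox7a2 (-0.23, SE 0.09). The call ended without KO replicate 2 (adjusted p = 0.267). No member of these 4 lists passed adjusted over the list alone.

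General hepatocyte markers (15 of 18 negative, median -0.13, camera adjusted p = 0.0235), periportal genes (15 of 18 negative, median -0.14, adjusted p = 0.0309) and lipoprotein export genes (14 of 18 negative, median -0.15, adjusted p = 0.0327) also fell as lists, each with an adjusted p = 0.570 with an estimated correlation. Pck1, the gluconeogenic enzyme that belongs to the first and the second of these lists, was at 2374 ± 384 CPM in WT and 1463 ± 226 CPM in KO liver (SD, n = 3), a log2 fold change of -0.70 (SE 0.19). Hnf4a, the hepatocyte nuclear receptor, was at -0.34 (SE 0.17), the periportal cadherin Cdh1 at 0.36 (SE 0.10), Apoa4 at -0.70 (SE 0.28) and Tm6sf2, which helps to load lipid onto lipoproteins, at -0.44 (SE 0.21). No member passed adjusted over its list alone. Without KO replicate 2 none of these 3 lists passed (adjusted p = 0.219, 0.285 and 0.566 in the order given), nor did they without WT replicate 1 (0.129, 0.633 and 0.291). The hepatocyte list also lost its call without WT replicate 3 (0.0605) and without the 20 most abundant genes (0.0585).

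Cell cycle genes fell as a list, with 23 of 29 negative and a median of -0.25 (camera adjusted p = 2.49e-06; adjusted p = 0.570 with an estimated correlation). Ccnb1, the mitotic cyclin B1, was at 16.2 ± 1.93 CPM in WT and 10.9 ± 0.400 CPM in KO liver (SD, n = 3). The spindle gene Tpx2 had a log2 fold change of -0.45 (SE 0.12). None of the 29 passed adjusted over the list alone. p53 targets and senescence genes fell, with 11 of 15 negative and a median of -0.16 (camera adjusted p = 0.00232; adjusted p = 0.570 with an estimated correlation). Bbc3, the proapoptotic gene of PUMA, was the 1 member that passed adjusted over the list alone (adjusted p = 0.0366 in the list), with a log2 fold change of -0.54 (SE 0.12), and Btg2 was at -0.45 (SE 0.16). Without WT replicate 3 the p53 list did not pass (adjusted p = 0.120). Immediate early and heat shock genes, which respond to handling as well as to signals, fell with 15 of 19 negative and a median of -0.17 (camera adjusted p = 0.00232; adjusted p = 0.570 with an estimated correlation), including the phosphatase Dusp1 (-0.78, SE 0.21) and Zfp36 (-0.38, SE 0.14). Their mean log2 fold change went from -0.21 to -0.13 without WT replicate 3 and to -0.10 with 1 surrogate variable. The developmental signalling list of PDGF, hedgehog, Wnt, Notch and YAP genes rose, with 19 of 25 positive and a median of 0.11 (camera adjusted p = 0.0165; adjusted p = 0.570 with an estimated correlation). The Notch ligand Jag1 (0.28, SE 0.09) and the Wnt antagonist Sfrp1 (0.88, SE 0.32) had the smallest p in it, and its call ended without WT replicate 1 (adjusted p = 0.0564) and with 1 surrogate variable in the model (0.0636). No immediate early or developmental signalling gene passed adjusted over its list alone.

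Acute phase, neutrophil and blood genes, which varied widely between libraries of the same genotype, fell as lists as well. Acute phase genes had 21 of 25 negative and a median of -0.22 (camera adjusted p = 0.0133; adjusted p = 0.664 with an estimated correlation), with Socs3 at -0.94 (SE 0.46) and Mt1 at -1.62 (SE 0.83). Neutrophil markers had 14 of 15 negative and a median of -0.80 (camera adjusted p = 0.0329; adjusted p = 0.664 with an estimated correlation), with Cxcr2 at -0.85 (SE 0.64) and Il1r2 at -0.93 (SE 0.80). Erythroid genes had 8 of 8 negative and a median of -0.91 (camera adjusted p = 0.00356; adjusted p = 0.570 with an estimated correlation), and the haemoglobin genes Hbb-bt (-1.07, SE 0.54) and Hba-a2 (-0.91, SE 0.50) have near-identical partners that can share reads. Without WT replicate 3 none of the 3 passed in the same direction (adjusted p = 0.751 for acute phase, 0.222 with the opposite sign for neutrophil and 0.751 for erythroid genes). The mean log2 fold change of acute phase genes, -0.25 over all libraries, changed sign without WT replicate 3 (0.13) or KO replicate 3 (0.021), was -0.021 without KO replicate 1 and -1.22 without KO replicate 2. That of neutrophil genes, -0.68 over all libraries, was 0.31 without WT replicate 3 and -1.59 without KO replicate 2. Acute phase and neutrophil genes also lost the call without WT replicate 1 (0.219 and 0.0569), KO replicate 1 (0.408 and 0.358) or KO replicate 3 (0.786 and 0.412). The direction of the acute phase and neutrophil lists turned with 1 surrogate variable in the model (adjusted p = 0.00361 and 4.42e-08), where the erythroid list did not pass (0.807). That of the neutrophil list also turned with the acute phase level as a covariate (0.896). The neutrophil call also ended under limma-voom (adjusted p = 0.232), the robust fit (0.0588) and the stricter count filter (0.0527). No member of the 3 lists passed adjusted over its list alone.

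Sex chromosome markers passed as a list (4 of 5 positive, median 0.12, camera adjusted p = 0.00356; adjusted p = 0.570 with an estimated correlation), and Xist was the member that passed adjusted over the list alone (adjusted p = 0.00345 in the list). Xist was at 1.29, 1.01 and 0.765 CPM in the WT and 4.97, 5.12 and 2.18 CPM in the KO libraries. The Y-linked members lay between -0.06 and 0.28 on the log2 scale, with Eif2s3y at 0.28 (SE 0.14), so all 6 libraries carried Y-linked RNA at similar levels. Xist lies on chromosome X of GRCm38 (103460366 to 103483254, minus strand) opposite its antisense partner Tsix, and the strand setting used for counting is not given in the sources used here, so reads of the pair are uncertain.

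The other 19 lists did not pass camera's preset test. Values nearest to the threshold were those of monocyte-derived and lipid-associated macrophages (15 of 18 positive, median 0.08, adjusted p = 0.0578) and NRF2 and oxidative stress genes (16 of 21 negative, median -0.09, adjusted p = 0.0762). The macrophage list passed under limma-voom (adjusted p = 0.0430), the stricter count filter (0.0419), scaling by library size (0.0133) or upper quartile (0.0336), the acute phase covariate (0.00141) and 1 surrogate variable (1.68e-05). NRF2 (0.0427) and adipose genes (0.00766) passed without a count filter. Fetal and tumour genes had a median of 0.08 (adjusted p = 0.134), unfolded protein response genes -0.07 (0.176), adipose and mesothelial genes 0.44 (0.176), bile acid genes -0.10 (0.218) and cholesterol synthesis genes -0.05 (0.221). Interferon-stimulated genes had a median of 0.08 (adjusted p = 0.284), inflammatory cytokines and chemokines -0.09 (0.320), Eph receptors and ephrins 0.13 (0.353), pericentral genes -0.03 (0.447), xenobiotic metabolism genes 0.06 (0.537), B and plasma cells 0.13 (0.537) and vascular endothelium -0.07 (0.545). In fatty acid and triglyceride synthesis the median was -0.02 (adjusted p = 0.676), and Srebf1 alone of its 23 members passed adjusted over the list alone (adjusted p = 0.0164 in the list). The signs of median, mean and test differed for female-biased genes (median 0.04, mean -0.17, test lower, adjusted p = 0.369), clock genes (0.01, -0.0053, test lower, 0.412), T and NK cells (0.13, -0.0036, test higher, 0.537) and male growth-hormone-dependent genes (-0.02, -0.11, test higher, 0.956). Scaling to library size alone turned the direction of the T and NK cell (adjusted p = 0.939), xenobiotic (0.887) and male-biased lists (0.567).

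Several of these 19 lists passed camera's preset test once a library was left out. Without WT replicate 1 these were interferon-stimulated (adjusted p = 3.13e-09), unfolded protein response (0.0213) and male-biased genes (0.00150), and without WT replicate 2 xenobiotic genes (0.0122). Without WT replicate 3 they were pericentral (2.05e-09), bile acid (3.42e-06), monocyte-derived macrophage (0.000103), NRF2 (0.00146), cholesterol (0.00256), fetal and tumour (0.0223), adipose and mesothelial (0.0398) and T and NK cell genes (0.0419). Xenobiotic (0.000147) and male-biased genes (0.00218) passed there with the direction turned. Without KO replicate 1 they were monocyte-derived macrophage (0.00260), fetal and tumour (0.0188), female-biased (0.0230), NRF2 (0.0335), adipose and mesothelial (0.0344), bile acid and cytokine genes (0.0398 each). Without KO replicate 2 cholesterol (3.12e-05) and xenobiotic genes (0.00232) passed, and without KO replicate 3 adipose and mesothelial genes (0.0447).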

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

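The acute phase covariate and the surrogate variable were chosen after the data were seen, and the cause of the changed results below was not tested. Ephb2 kept its sign, at -0.63 to -0.27 over all settings (adjusted p 0.427 to 1.00). Over 75 named genes and their settings, 1424 values held 11 newly past the threshold and 10 of the other sign. Of 858 list values, 689 stayed on their side, 83 lost the call, 47 gained it and 39 turned direction, and 8 of the 22 passing lists kept the call under every setting except the estimated correlation and fry. The count of genes by edgeR was 0 (886 at an unadjusted p under 0.05, with 0 by limma-voom). It was 3 without a count filter, 3 of them lower in KO liver, 8 by DESeq2 (3 higher, 5 lower), and 0 to 2 with a library left out (0 to 1 higher, 0 to 1 lower), the 2 being Mir6236 and Mup19 without WT replicate 3. An adjusted p under 0.1 and a test against a fold of 1.5 gave 0. The replicate numbers showed no pairing of the samples in these counts (correlations of same-numbered deviations -0.03, -0.44 and -0.31), and no sample of replicates 1 to 3 correlated best with its own number. The labels do not say whether a number marks a shared litter, cage or day, so a pairing is not excluded. With the replicate block 0 genes passed, and Saa1 turned to -1.33. Under the block the neutrophil (adjusted p = 0.0640) and quiescent stellate lists (0.0689) did not pass and the monocyte-derived macrophage list did (0.0466).

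Scaling by library size shifted the median of all genes to 0.07 and turned T and NK cell (adjusted p = 0.939), xenobiotic (0.887) and male-biased genes (0.567). Male-biased genes also turned with upper-quartile scaling (0.784) and robust fitting (0.954), female-biased genes without a count filter (0.560) and B cells with the stricter filter (0.920). limma-voom turned Saa1 to -0.28. With the estimated correlation the matrix and TGF-beta lists had an adjusted p of 0.570 each, and by fry 0.568 and 0.517. The acute phase covariate brought matrix remodelling (0.0141), monocyte-derived macrophages (0.00141), adipose (0.00496), NRF2 (0.0224), bile acid (0.0251), female-biased (0.0251) and pericentral genes (0.0357) past the threshold. It turned vascular endothelium (0.896), neutrophils (0.896), xenobiotic (0.133) and male-biased genes (0.645), and the acute phase list has no value there because the covariate is its own level. The surrogate variable brought matrix remodelling (0.000564), macrophages (1.68e-05), adipose (0.000326), NRF2 (0.00258), bile acid (0.000114), pericentral (3.08e-06) and fetal genes (0.0170) past it. It turned vascular endothelium (0.181), neutrophils (4.42e-08), acute phase (0.00361), fatty acid synthesis (0.937), xenobiotic (4.42e-08) and male-biased genes (0.0123), as well as Il1r2 (0.26), Col3a1 (-0.067), Acta2 (0.0063) and S100a8 (0.51). DESeq2 gives no list tests.

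Leaving out 1 library also moved list means by over 1.5 times. Without WT replicate 3 the mean log2 fold change went from -0.25 to -0.11 for sinusoidal endothelium (-0.16 without KO replicate 3), -0.20 to -0.062 for p53, -0.82 to -0.020 for erythroid and 0.088 to 0.14 for TGF-beta genes (0.024 without WT replicate 1, 0.053 without KO replicate 2). Without KO replicate 1 it went from 0.32 to 0.15 for dendritic cell, -0.11 to -0.17 for oxidative phosphorylation (-0.042 without KO replicate 2) and -0.092 to -0.14 for lipoprotein genes (-0.046 without WT replicate 1, -0.035 without KO replicate 2). Without WT replicate 2 it went from 0.14 to 0.28 for developmental signalling and -0.16 to -0.25 for periportal genes (-0.059 without WT replicate 1). The acute phase mean of -0.25 went to -0.17, -0.58 and 0.13 without WT replicates 1 to 3 and to -0.021, -1.22 and 0.021 without KO replicates 1 to 3. The neutrophil mean of -0.68 went to -1.11 without WT replicate 2, 0.31 without WT replicate 3, and -0.42, -1.59 and -0.39 without KO replicates 1 to 3. With 1 surrogate variable the matrix mean of 0.17 went to 0.081, sinusoidal endothelium from -0.25 to -0.15 and p53 genes from -0.20 to -0.13.

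With a library left out, log2 fold changes ran from -0.043 to 0.43 for Col3a1, -1.79 to 0.36 for Il1r2, -1.60 to 0.44 for S100a8 and -2.38 to 1.49 for Saa1. Adjusted p ran from 6.97e-08 to 0.725 for matrix proteins, 0.00688 to 0.494 for TGF-beta, 0.0398 to 0.549 for activated stellate cells, 0.0186 to 0.731 for matrix remodelling, 7.1e-07 to 0.412 for neutrophils, 0.0419 to 0.700 for T and NK cells and 0.0565 to 0.990 for vascular endothelium. It ran from 0.0344 to 0.888 for adipose, 3.42e-06 to 0.862 for bile acid, 3.12e-05 to 0.606 for cholesterol, 0.288 to 0.687 for fatty acid synthesis and 2.05e-09 to 0.773 for pericentral genes. For xenobiotic genes it was 0.000147 to 0.991, for interferon-stimulated genes 3.13e-09 to 0.495, for male-biased genes 0.00150 to 0.942 and for female-biased genes 0.0230 to 0.951.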

Other observations

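The tests of other splits by edgeR, of residual blood, of feeding, of the acute phase covariate and of the stellate cell share were chosen only after the results they bear on were seen. Between the genotypes edgeR called 0 genes, so all 10 of 10 splits of the 6 libraries into 3 and 3 give at least as many by construction, which says nothing about chance (886 genes at an unadjusted p under 0.05, with 0 by limma-voom and 8 by DESeq2). The highest other split gave 200. DESeq2 called at least as many as its 8 genes in 3 of 10 splits, with 644 in the highest other split. At least as many gene lists as the 22 of the genotypes passed camera's preset test in 1 of 10 splits, with 21 in the highest other. The splits are too few for a share under 0.05.

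The split with 200 genes, WT replicates 1 and 3 and KO replicate 2 against the rest, crosses the genotypes and points to a structure of the samples, with 157 genes higher in those libraries and 43 lower, among them the neutrophil protease gene Prtn3, the hepatocyte genes Fgl1 and Orm2 and Lcn2, which both the acute phase and the neutrophil list hold (log2 differences 4.31, 2.08, 3.51 and 2.90). A difference in depth is argued against by the 203 genes called after every library was thinned to the smallest total, and a few dominant genes by the 197 called without the 20 most abundant ones. Blood left in the tissue would not bring hepatocyte transcripts, and 20 of 25 acute phase genes were called, so it cannot be the whole cause. Blood genes followed the same libraries, with Hbb-bs at 152, 435 and 157 CPM against 80.2, 94.9 and 100.0 CPM, though 0 of 8 were called by edgeR, so a part from blood stays open. An acute inflammatory response in some animals is a candidate explanation that stays open, and no biological explanation was tested because the labels give no group that follows this split.

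Genes induced in the fasted liver, such as Pdk4, Angptl4, Pck1 and Igfbp1 (log2 fold change -0.96, SE 0.34), lay lower in KO liver while Srebf1, induced by feeding, lay higher. A difference in feeding before collection may account for both. Over 20 fasting-induced genes the mean log2 fold change was -0.48 (95% interval -1.001 to 0.03), and over 18 feeding-induced genes it was 0.12 (SE 0.18, 95% interval -0.38 to 0.63). Both intervals include 0, the lists were written after the pattern was seen and hold the genes that prompted them, so feeding and genotype cannot be told apart here. An effect of the genotype stays open.

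Matrix genes lay higher in KO liver by a mean of 0.19 (95% interval -0.27 to 0.65) over the libraries, and bile duct markers by 0.37 (95% interval -0.037 to 0.77). With the acute phase level as a covariate the mean was 0.13 (SE 0.13, 95% interval -0.28 to 0.53), too wide to say whether an uneven spread of that response could produce it. A larger share of stellate cells in an unchanged state would raise quiescent markers too. These markers follow the state of the cells as well as their number, so they cannot measure the share alone. The quiescent mean was -0.17 (95% interval -0.35 to 0.01), and the matrix mean exceeded it by 0.37 (SE 0.17, 95% interval -0.09 to 0.83). These intervals include 0, so neither explanation can be settled with 3 libraries per genotype. An effect of the genotype on matrix genes stays unresolved, since the list tests differed. The adjusted p was 0.00245 by camera with the preset correlation, 0.570 with an estimated correlation and 0.568 by fry.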
